A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

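Total RNA from 8 cultures of Saccharomyces cerevisiae BY4742 was extracted with acid phenol, labelled with biotin per the labels and hybridised to Affymetrix yeast arrays. The cultures formed 4 groups of 2 biological replicates by the titles: control, carnitine, peroxide (0.4 mM, 30 min) and carnitine with peroxide. With 2 cultures per group the p-values measure the spread between cultures of a group, pooled over the 4 groups. The deposited values are linear intensity, one signal per probe set and array, scaled by the authors; the summary method, background correction and scaling are not given in the sources used here. The software GCOS is named per the submitters' processing notes, without a version. The file held 10928 probe sets with values from 3.205 to 79918, and 0 of its value columns went unused.

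Probe sets were named from the platform table: 5498 carried exactly 1 S. cerevisiae gene, 1746 belonged to fission yeast, 1 to several genes, and 3683 had no gene listed, of which 213 were control or reporter probe sets. The 5498 covered 5449 genes; for genes with several probe sets the one with the highest mean log2 signal was used, which left out 49, and 12 symbols were updated through the gene identifier. Of 41 genes with several probe sets above the floor, 0 had called peroxide effects of opposite sign (limma), and 109 tested genes have a probe set that also matches another gene. Reference tables were used for names only. The floor was the 95th percentile of the mean log2 signal of the fission yeast probe sets, 2.051 (4.145 on the linear scale; their median was 3.838 and their highest mean 4.951); 125 genes below it were dropped and 5324 tested. Signals were used as deposited where array medians lay within 10% of each other. The medians of the tested genes met this (spread 5.08%), while those of all 10928 probe sets, most of them near the floor, did not (61.1%); the first was applied, and quantile normalization was run as an alternative.

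Log2 signals were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) with a mean for each group over all 8 arrays, giving 4 residual degrees of freedom and 3.443 prior ones. There were 6 comparisons: carnitine against control, peroxide against control, peroxide with carnitine against carnitine, carnitine with peroxide against peroxide, the interaction, and the carnitine effect averaged over both peroxide conditions. Adjusted p is Benjamini-Hochberg within a comparison, with a threshold of 0.05. For 39 of 40 fixed gene lists with at least 4 tested members, camera was run with its preset correlation of 0.01 and with an estimated correlation, and fry beside it, which called 0, 34, 33, 17, 4 and 5 lists in the order of the comparisons. The size of the peroxide response was compared by a total least squares slope with a jackknife over the 8 arrays. Genes at the floor in one of 2 groups compared are given as a bound of fold change against the floor.

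Groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took, in each comparison, the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap (this last condition not for the interaction and the averaged effect), up to 4 members of a list by absolute moderated t, and a fixed set of genes of carnitine use, antioxidant defence, mating type and auxotrophy. The alternatives were quantile normalization, median centring, no filter, a filter at the 40th percentile (mean log2 of 11.06), no trend in the variance, an offset of 50, only the arrays of the comparison, a block for replicate number, a 2-fold minimum, an adjusted p of 0.10, all probe sets, and leaving out each array. Scaling to poly-A or hybridisation spikes and crossing the numbers of the carnitine arrays were added later. On 5324 simulated genes the pipeline recovered 86.6% of 1.5-fold and 100% of 2-fold changes for carnitine alone. For the interaction they were 56.7% and 91.0%. False calls were 8 of 199 and 8 of 172. These rates hold for the simulated noise only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets of fission yeast and those with no gene listed were left out of the comparisons, and no genome sequence or position was used.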

Results

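Carnitine, a quaternary amine that carries activated acetyl and fatty acyl groups between cell compartments, was given to budding yeast with and without hydrogen peroxide, and transcript levels were read on 8 Affymetrix arrays. The strain was BY4742, a haploid laboratory strain of Saccharomyces cerevisiae with deletions in HIS3, LEU2, LYS2 and URA3, grown in synthetic complete dextrose medium to mid-log phase. There were 4 groups of 2 arrays, each array from its own culture: untreated control, carnitine, peroxide (0.4 mM for 30 min) and carnitine with peroxide. The carnitine dose is 100 mg/L in the series design and 1000 mg/L in the treatment protocol, and both statements cover the same cultures. The 2 arrays per group limit the precision of every estimate. The deposited linear signals ran from 3.205 to 79918, and the array medians over the 5324 tested genes lay between 3044 and 3198. Between 5300 and 5313 of these genes lay above the floor on each array. Changes are log2 differences ± SE from the fit over all 8 arrays, group signals are means ± SD of 2 arrays, and a gene rose or fell where its limma adjusted p was below 0.05.

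Signals of the marker genes matched the strain name but not one part of the recorded genotype. LEU2, LYS2 and URA3 read between 3.87 and 4.09 on all 8 arrays, the level of probe sets for another species. HIS3 read 10505 to 17056, and whether its probes lie in the deleted part is not given in the sources used here, so HIS3 checks nothing. The genotype field reads MATa, whereas the α pheromone genes MF(ALPHA)1 and MF(ALPHA)2 read 46478 to 51980 and 25016 to 37795. STE3, the receptor that α cells carry, read 16046 to 27503, while the a-cell genes MFA1 and STE2 read 82.0 to 166 and 84.3 to 241. Replicate arrays differed by a median absolute log2 difference of 0.0865 to 0.0984. The first principal component held 89.4% of the variance and separated peroxide from no peroxide; the second held 6.64% and separated peroxide from carnitine with peroxide.

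**Figure D1:**
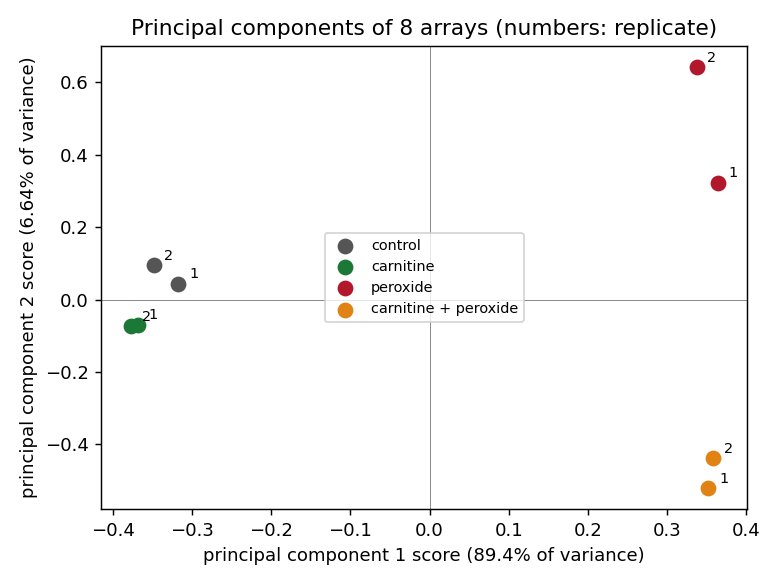
Principal components of the log2 signals of 5324 genes on 8 arrays. The x axis is component 1 (89.4% of the variance) and the y axis component 2 (6.64%), both unitless scores; each point is 1 array, coloured by group (control, carnitine, peroxide, carnitine with peroxide; n = 2 each). The 4 arrays with peroxide lie to the right, and carnitine separates the peroxide arrays along component 2 more than the arrays without peroxide.

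All changes are relative to the overall array signal. Poly-A spikes are bacterial transcripts added to the RNA. Scaling to them moved the median of all genes by 0.11, -0.53, 0.12, 0.76, 0.65 and 0.44 in the order of the comparisons. Hybridisation spikes, added with the labelled material, moved it by 0.19, 0.48, 0.35, 0.06, -0.13 and 0.12 in the same order. Replicates differed by up to 0.501 in mean poly-A and 0.297 in mean hybridisation spike signal. The poly-A gap is close to the -0.53 for peroxide and exceeds the 0.11 and 0.12. A list whose median change is smaller than such a shift and opposite in sign has no set absolute direction. Medians of 23 of 96 list results changed sign under poly-A and 11 under hybridisation scaling. Each of the 120 named gene results used for the comparisons passed in the same direction under both spike scalings.

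Carnitine without peroxide, compared with control, answers which transcripts respond to carnitine in unstressed cells: single phosphate and iron genes fell, HES1, TIR2 and ZRT1 rose, and camera placed 5 lists lower and 4 higher, ribosome biogenesis with the lowest p, though 0 with an estimated correlation. SPL2 (YHR136C), which encodes a regulator of phosphate transport, fell by 2.46 ± 0.23 (adjusted p = 0.00688), from 426 ± 109 to 76.4 ± 3.18. PHO84 (YML123C), the high-affinity phosphate transporter gene, fell by 1.83 ± 0.17 (adjusted p = 0.00688), from 4538 ± 519 to 1287 ± 290.3, and PHO89 (YBR296C), for a sodium-coupled phosphate transporter, fell by 2.44 ± 0.38 (adjusted p = 0.0301). ENB1 (YOL158C), which encodes a siderophore transporter, fell by 1.56 ± 0.20 (adjusted p = 0.0175), and FRE3 (YOR381W), for a reductase that frees siderophore iron, fell by 1.26 ± 0.18 (adjusted p = 0.0228). HSP30 (YCR021C), for a membrane heat-shock protein that restrains the proton pump, fell by 1.65 ± 0.23 from 4870.2 ± 798 to 1605 ± 617 (adjusted p = 0.0216).

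The largest of the named rises was that of HES1 (YOR237W), of the oxysterol-binding family, by 1.56 ± 0.28 (adjusted p = 0.0461). The wall mannoprotein genes TIR2 (YOR010C) and HPF1 (YOL155C) rose by 1.48 ± 0.11 and 1.44 ± 0.14, HPF1 from 935 ± 8.13 to 2540.2 ± 318 (adjusted p = 0.00728). ZRT1 (YGL255W), for the high-affinity zinc transporter, rose by 1.09 ± 0.12 (adjusted p = 0.00894) and DUR3 (YHL016C), for a urea and polyamine transporter, by 0.98 ± 0.096 (adjusted p = 0.00698). The peroxiredoxin gene TSA2 (YDR453C) rose by 0.96 ± 0.13 (adjusted p = 0.0209), NCA3, of the SUN family, by 1.06 ± 0.15, the sporulation-linked SPS4 by 1.32 ± 0.097, and YGR079W by 0.88 ± 0.11. SNO4 rose by 1.05 ± 0.18 on a probe set that also matches another gene. Among further falls, BAG7 fell by 1.75 ± 0.31, YER053C-A fell by 1.52 ± 0.17, YNL092W fell by 1.45 ± 0.11 and CYC7, for the minor cytochrome c, fell by 1.30 ± 0.23. Smaller falls were those of CIT1, for mitochondrial citrate synthase, which fell by 0.37 ± 0.043, IDH1, for isocitrate dehydrogenase, fell by 0.46 ± 0.071, and NDE1, for an NADH dehydrogenase facing the cytosol, fell by 0.38 ± 0.056. With 50 added to each signal before the log2 step, the changes of SPS4, PHO89, BAG7 and YNL092W shrank to 0.61, -1.54, -0.50 and -0.92.

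Of the 28 iron regulon genes, 0 rose, 5 fell and 23 did not pass, with 1 and 12 when adjusted over the list alone. The surface reductase gene FRE1 fell by 1.02 ± 0.095, TIS11, which speeds decay of iron-related transcripts, fell by 0.98 ± 0.13 and the oxidase gene FET3 fell by 0.50 ± 0.072. The list lay below the other genes in camera (median -0.26, adjusted p = 5.49e-08, adjusted p = 0.500 with an estimated correlation). Among 16 phosphate regulon genes, 0 rose, 3 fell and 13 did not pass (0 and 6 adjusted over the list alone, median -0.10, mean -0.56), and camera placed them lower, at adjusted p = 9.61e-05 and adjusted p = 0.427 with an estimated correlation. None of the 18 trehalose and glycogen genes passed over all genes, 0 rose and 8 fell adjusted over the list alone, and the median was -0.33 (adjusted p = 5.06e-05, adjusted p = 0.561 with an estimated correlation); the trehalase gene ATH1 had -0.59 ± 0.11 and the glycogen branching gene GLC3 -0.81 ± 0.21. Ribosome biogenesis, with 93 genes, had 2 that rose, 0 that fell and 91 that did not pass, against 19 and 0 adjusted over the list alone, and a median of 0.17. The nucleolar genes LCP5 and ENP2 rose by 0.48 ± 0.074 and 0.25 ± 0.045, and camera placed the list higher (adjusted p = 2.52e-20, adjusted p = 0.427 with an estimated correlation). No G1/S cell cycle gene of 28 passed (0 adjusted over the list alone), yet camera placed the list higher (median 0.22, adjusted p = 1.51e-06, adjusted p = 0.427 with an estimated correlation); the cyclin genes CLB5 and PCL1 had 0.44 ± 0.10 and 0.73 ± 0.18. RNA polymerase I and III genes (27; 0 passed in all, 0 over the list alone, median 0.12) were also placed higher, at adjusted p = 0.000725 and adjusted p = 0.500 with an estimated correlation. So were the 16 genes of daughter-cell separation and early G1, with 0 passing over all genes and 2 that rose adjusted over the list alone (median 0.15, adjusted p = 0.000961, adjusted p = 0.427 with an estimated correlation). Autophagy (24 genes, 0 passing, 0 over the list alone, median -0.13) was placed lower, at adjusted p = 0.0190 and adjusted p = 0.500 with an estimated correlation. Chaperones were placed lower as well (adjusted p = 0.0438, adjusted p = 0.791 with an estimated correlation), with 1 of 26 that rose, 2 that fell and 23 that did not pass (1 and 5 adjusted over the list alone, median -0.05); HSP42, for a small heat-shock protein, fell by 1.11 ± 0.11 while HSP31 rose by 0.34 ± 0.056. The tricarboxylic acid cycle list did not pass, with 0 that rose and 2 that fell of 18 (0 and 3 adjusted over the list alone, median -0.01, adjusted p = 0.119, adjusted p = 0.569 with an estimated correlation). Nor did the respiratory chain (0 and 2 of 34, 0 and 2 adjusted over the list alone, median -0.06, adjusted p = 0.164, adjusted p = 0.932 with an estimated correlation) or cell wall integrity (0 and 1 of 19, 0 and 1 adjusted over the list alone, median 0.04, adjusted p = 0.546, adjusted p = 0.984 with an estimated correlation). Of the 6 carnitine shuttle genes, 0 passed over all genes and 1 fell adjusted over the list alone (median -0.17, adjusted p = 0.119, adjusted p = 0.500 with an estimated correlation).

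The linear model called 80 of 5324 genes, 25 that rose and 55 that fell, with 22 changed at least 2-fold and 772 at unadjusted p below 0.05. Camera called 9 of 39 lists with the preset correlation and 0 with correlation estimated from the arrays, where 4 lists had unadjusted p below 0.05. Leaving out 1 array lowered the number of genes to between 17 and 54, and the calls of HES1, SNO4, PHO89, BAG7 and CYC7 also ended when no trend was put on the variance.

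Peroxide without carnitine, compared with control, answers how cells respond to 30 min of peroxide: 28 of 31 antioxidant and 20 of 20 Yap1-linked genes rose, and 20 of 21 G2/M and 90 of 93 ribosome biogenesis genes fell. SRX1 (YKL086W), for sulfiredoxin, which reactivates oxidised peroxiredoxins, rose by 12.18 ± 0.16 (adjusted p = 9.66e-09), from 4.63 ± 0.0728 to 21530 ± 352. Its control signal lay below the highest mean of a fission yeast probe set, 4.951, so the size of this rise depends on the floor. FRM2 (YCL026C-A), of the nitroreductase family, rose by 10.71 ± 0.14, from 13.7 ± 0.402 to 22876 ± 2016. OYE3 (YPL171C), for an NADPH oxidoreductase, rose by 9.64 ± 0.12, and GTT2 (YLL060C), for a glutathione transferase, by 7.01 ± 0.12, from 216 ± 32.6 to 27664 ± 222. PCL1 (YNL289W), a G1 cyclin gene, fell by 6.79 ± 0.18, from 634 ± 73.1 to 5.72 ± 0.629, and CLB2 (YPR119W), the main mitotic cyclin gene, fell by 5.28 ± 0.48, from 2211 ± 38.8 to 67.2 ± 50.6, whereas the G1 cyclin gene PCL2 rose by 1.41 ± 0.22.

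The peroxisomal catalase gene CTA1 (YDR256C) rose by 7.44 ± 0.31 and the cytosolic catalase gene CTT1 (YGR088W) by 4.94 ± 0.34 (adjusted p = 8.81e-06). YDL218W rose by 8.63 ± 0.18, LSO1 by 6.58 ± 0.26 and DAK2, for a dihydroxyacetone kinase, by 8.44 ± 0.16. YKL107W and GTO3 (YMR251W), the latter for an omega-class glutathione transferase, were at the floor in control and rose at least 125-fold (adjusted p = 4.12e-07) and at least 90.8-fold (adjusted p = 1.52e-08). YAP1, for the transcription factor that senses peroxide, rose by 1.997 ± 0.093, GSH1, for the first step of glutathione synthesis, by 1.78 ± 0.050, TRR1, for thioredoxin reductase, by 1.02 ± 0.060 and TRX2, for thioredoxin, by 0.48 ± 0.036. SOD2, for mitochondrial superoxide dismutase, rose by 2.65 ± 0.050 and the cytosolic SOD1 by 0.36 ± 0.040, whereas SKN7, for a second peroxide-responsive regulator, fell by 1.07 ± 0.080. GIC1, for an effector of bud polarity, fell by 7.85 ± 0.46, the G1 cyclin gene CLN1 fell by 4.89 ± 0.28, and NRM1, for a repressor of late G1 transcription, fell by 5.396 ± 0.23. The early cell-cycle repressor genes YOX1 and YHP1 fell, with changes of -5.35 ± 0.32 and -4.76 ± 0.55, TOS6 fell by 4.93 ± 0.49, YMR230W-A fell by 6.81 ± 0.17, and VAC17, for vacuole inheritance, fell by 4.65 ± 0.29. With 50 added to the signals the changes shrank to 5.33 for YDL218W, 4.82 for DAK2, 3.44 for LSO1, -4.66 for GIC1, -3.61 for PCL1, -3.18 for YOX1 and -4.07 for YMR230W-A.

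Among genes of carnitine use, CAT2, for the mitochondrial and peroxisomal carnitine acetyltransferase, rose by 2.21 ± 0.14, YAT2, for a cytosolic one, by 1.78 ± 0.12, CIT2, for peroxisomal citrate synthase, by 1.54 ± 0.11 and AGP2, for the plasma membrane carnitine transporter, by 2.11 ± 0.30. HNM1, which encodes the choline transporter, fell by 2.19 ± 0.12. Of the 6 carnitine shuttle genes 4 rose, 0 fell and 2 did not pass (4 and 0 adjusted over the list alone). The carnitine shuttle median was 1.66 (camera adjusted p = 0.0454, adjusted p = 0.390 with an estimated correlation). All 20 Yap1-linked oxidoreductase and efflux genes passed, 20 rising (20 adjusted over the list alone), among them HBN1 by 5.72 ± 0.10. The Yap1-linked median was 3.21 (camera adjusted p = 3.43e-10, adjusted p = 0.282 with an estimated correlation). Peroxide and thiol antioxidants gave 28 of 31 that rose and 3 that fell (28 and 3 adjusted over the list alone), with TSA2 up by 6.17 ± 0.13 and GPX2, for a glutathione peroxidase, by 2.18 ± 0.049. The antioxidant median was 1.02 (camera adjusted p = 3.51e-07, adjusted p = 0.282 with an estimated correlation). In the chaperone list 25 of 26 rose and 0 fell (25 and 0 adjusted over the list alone), SSA4, for a stress-induced Hsp70, by 4.19 ± 0.059 and its partner SSE2 by 3.76 ± 0.071. The chaperone median was 1.43 (camera adjusted p = 1.63e-08, adjusted p = 0.282 with an estimated correlation). Every one of the 36 proteasome genes rose (36 over all genes, 36 over the list alone), as with RPN2, for a regulatory subunit, by 0.95 ± 0.055. The proteasome median was 0.64 (camera adjusted p = 8.73e-09, adjusted p = 0.463 with an estimated correlation). General stress genes rose in 25 of 29 cases and fell in 1 (25 and 1 adjusted over the list alone), including GAD1, for glutamate decarboxylase, by 3.25 ± 0.12. The general stress median was 1.65 (camera adjusted p = 3.51e-07, adjusted p = 0.411 with an estimated correlation). The iron regulon gave 22 of 28 that rose and 0 that fell (22 and 0 adjusted over the list alone), FRE1 by 4.95 ± 0.095 and FIT3, for a wall protein that holds siderophores, by 3.49 ± 0.11. The iron regulon median was 1.43 (camera adjusted p = 3.51e-07, adjusted p = 0.390 with an estimated correlation).

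Autophagy genes rose in 19 of 24 cases (20 and 0 adjusted over the list alone), ATG8, for the membrane-linked ubiquitin-like protein, by 2.20 ± 0.15. The autophagy median was 1.08 (camera adjusted p = 2.73e-06, adjusted p = 0.282 with an estimated correlation). In the trehalose and glycogen list 12 of 18 rose and 4 fell (12 and 4 adjusted over the list alone): the trehalase gene NTH1 rose by 2.12 ± 0.060 and GSY1, for glycogen synthase, fell by 3.82 ± 0.23. The trehalose and glycogen median was 1.16 (camera adjusted p = 0.0423, adjusted p = 0.593 with an estimated correlation). Respiratory chain and ATP synthase genes gave 16 of 34 that rose and 5 that fell (15 and 5 adjusted over the list alone), CYC1, for the main cytochrome c, by 2.67 ± 0.071. The respiratory chain median was 0.20 (camera adjusted p = 0.0423, adjusted p = 0.593 with an estimated correlation). DNA damage genes rose in 14 of 22 cases and fell in 4 (14 and 4 adjusted over the list alone), RNR3, for a damage-induced ribonucleotide reductase subunit, by 3.36 ± 0.22. The DNA damage median was 0.52 (camera adjusted p = 0.0150, adjusted p = 0.520 with an estimated correlation). Ribosome biogenesis fell, with 90 of 93 lower and 1 higher (90 and 1 adjusted over the list alone), and the helicase gene DRS1 fell by 1.30 ± 0.055 and UTP20, for a processing factor, fell by 1.76 ± 0.061. The ribosome biogenesis median was -1.03 (camera adjusted p = 5.64e-17, adjusted p = 0.282 with an estimated correlation). Of 128 cytosolic ribosomal protein genes 1 rose and 114 fell (1 and 115 adjusted over the list alone), and RPS28B fell by 1.25 ± 0.071. The cytosolic ribosomal median was -0.31 (camera adjusted p = 8.73e-09, adjusted p = 0.520 with an estimated correlation). RNA polymerase I and III genes fell in 24 of 27 cases and rose in 1 (24 and 1 adjusted over the list alone), and the subunit gene RPA49 fell by 1.18 ± 0.050. The polymerase I and III median was -1.07 (camera adjusted p = 9.51e-07, adjusted p = 0.282 with an estimated correlation). Translation factor genes gave 22 of 32 that fell and 1 that rose (22 and 1 adjusted over the list alone), and NIP1, for an initiation factor subunit, fell by 0.94 ± 0.051. The translation factor median was -0.39 (camera adjusted p = 0.000473, adjusted p = 0.390 with an estimated correlation). G2/M cell cycle genes fell in 20 of 21 cases (1 rose; 20 and 1 adjusted over the list alone), and the cyclin gene CLB1 fell by 3.48 ± 0.20 and the polo kinase gene CDC5 fell by 2.78 ± 0.17. The G2/M cell cycle median was -1.82 (camera adjusted p = 2.13e-05, adjusted p = 0.520 with an estimated correlation).

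All 9 histone genes fell (9 over all genes, 9 over the list alone), and the linker histone gene HHO1 fell by 1.56 ± 0.10. The histone median was -0.74 (camera adjusted p = 0.00287, adjusted p = 0.505 with an estimated correlation). Purine synthesis genes fell in 17 of 19 cases and rose in 2 (17 and 2 adjusted over the list alone), and the one-carbon gene MTD1 fell by 3.18 ± 0.19. The purine synthesis median was -1.03 (camera adjusted p = 0.000669, adjusted p = 0.520 with an estimated correlation). Phospholipid and choline genes fell in 17 of 20 cases and rose in 2 (17 and 2 adjusted over the list alone), and PSD1, for a decarboxylase that makes phosphatidylethanolamine, fell by 2.25 ± 0.072. The phospholipid and choline median was -0.97 (camera adjusted p = 0.00121, adjusted p = 0.411 with an estimated correlation). In fatty acid and ergosterol synthesis 21 of 30 fell and 3 rose (21 and 3 adjusted over the list alone), and ERG1, for squalene epoxidase, fell by 1.60 ± 0.062. The ergosterol list median was -0.51 (camera adjusted p = 0.000978, adjusted p = 0.411 with an estimated correlation). Genes of daughter-cell separation and early G1 gave 11 of 16 that fell and 1 that rose (12 and 1 adjusted over the list alone), and SUN4 fell by 1.30 ± 0.083. The daughter-cell list median was -0.73 (camera adjusted p = 0.0239, adjusted p = 0.390 with an estimated correlation). Outside the lists that passed, the hexose transporter gene HXT2 fell by 1.78 ± 0.085, MTH1, for a glucose-signalling repressor, fell by 3.32 ± 0.21, and MIG1, for the repressor of glucose-repressed genes, fell by 1.72 ± 0.12. The linear model called 3980 of 5324 genes, 1877 that rose and 2103 that fell, 1303 of them at least 2-fold, with 4087 at unadjusted p below 0.05. Camera called 21 of 39 lists, 0 with estimated correlation, where 6 had unadjusted p below 0.05. The calls of the trehalose and glycogen, translation factor, respiratory chain, and daughter-cell separation lists ended under both spike scalings.

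Peroxide in the presence of carnitine, compared with carnitine alone, answers whether the same response occurs in carnitine-fed cells: SRX1, FRM2 and OYE3 rose and 20 of 21 G2/M genes fell here as well. SRX1 rose by 11.58 ± 0.16 (adjusted p = 1.27e-08), FRM2 by 10.62 ± 0.14, OYE3 by 10.45 ± 0.12, to 18333 ± 786, and YDL218W by 9.89 ± 0.18. GND2 (YGR256W), for the minor 6-phosphogluconate dehydrogenase, which makes NADPH, rose by 7.92 ± 0.22 (adjusted p = 1.83e-07), from 12.1 ± 2.17 to 2929 ± 626. JLP1, for a sulfonate dioxygenase, rose by 7.86 ± 0.18, SPS100, for a spore wall protein, by 7.21 ± 0.34, LSO1 by 8.06 ± 0.26 and DAK2 by 8.04 ± 0.16. YKL107W, at the floor with carnitine alone, rose at least 126-fold. CLB2 fell by 6.39 ± 0.48, PCL1 fell by 7.26 ± 0.18, TOS6 fell by 7.49 ± 0.49 and SFG1 (YOR315W), for a regulator of filamentous growth, fell by 6.08 ± 0.35. HOF1 (YMR032W), which acts at the bud neck in cytokinesis, fell by 5.54 ± 0.25 (adjusted p = 1.24e-06), from 1213 ± 21.0 to 26.5 ± 7.05, and AIM20, GIC1, NRM1, YOX1 and YMR230W-A fell, with changes of -5.59 ± 0.32, -5.67 ± 0.46, -5.43 ± 0.23, -5.41 ± 0.32 and -6.84 ± 0.17. CAT2, YAT2 and CIT2 rose by 2.55 ± 0.14, 0.95 ± 0.12 and 1.52 ± 0.11, and HNM1 fell by 2.20 ± 0.12. With 50 added the changes shrank to 6.49 for YDL218W, 4.82 for LSO1, 4.43 for DAK2, 4.53 for JLP1, 3.62 for SPS100, -4.27 for PCL1 and -3.86 for YMR230W-A.

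Mitochondrial ribosomal protein genes, listed by their symbols, rose in 47 of 70 cases and fell in 2 (47 and 2 adjusted over the list alone). MRP8, a member by symbol only, rose by 1.41 ± 0.069. The mitochondrial ribosomal median was 0.33 (camera adjusted p = 0.000121, adjusted p = 0.475 with an estimated correlation). Of 47 amino acid biosynthesis genes under Gcn4, 8 rose, 28 fell and 11 did not pass (8 and 28 adjusted over the list alone), and ILV3, in branched-chain synthesis, fell by 1.75 ± 0.067. The Gcn4 list median was -0.29 (camera adjusted p = 0.0317, adjusted p = 0.664 with an estimated correlation). Without carnitine the mitochondrial ribosomal list did not pass, with 21 of 70 higher and 11 lower (16 and 10 adjusted over the list alone). The mitochondrial ribosomal median was 0.09 (camera adjusted p = 0.280, adjusted p = 0.805 with an estimated correlation). The Gcn4 list without carnitine gave 15 higher and 14 lower of 47 (15 and 14 adjusted over the list alone). The Gcn4 list median was 0.04 (camera adjusted p = 0.788, adjusted p = 0.950 with an estimated correlation). Respiratory chain genes with carnitine gave 13 higher and 7 lower of 34 (13 and 7 adjusted over the list alone). The respiratory chain median was 0.14 (camera adjusted p = 0.334, adjusted p = 0.777 with an estimated correlation). The iron regulon rose in 25 of 28 cases (25 and 1 adjusted over the list alone), TIS11 by 5.77 ± 0.13 and FRE1 by 6.11 ± 0.095. The iron regulon median was 1.96 (camera adjusted p = 4.09e-08, adjusted p = 0.325 with an estimated correlation). G2/M genes fell in 20 of 21 cases (20 adjusted over the list alone), and ALK1, for a mitotic kinase, fell by 4.23 ± 0.22. The G2/M cell cycle median was -2.75 (camera adjusted p = 2.50e-07, adjusted p = 0.414 with an estimated correlation). The linear model called 3987 of 5324 genes, 1906 that rose and 2081 that fell, 1359 of them at least 2-fold, with 4083 at unadjusted p below 0.05. Camera called 22 of 39 lists, 0 with estimated correlation, where 7 had unadjusted p below 0.05. The mitochondrial ribosomal and Gcn4 calls ended under both spike scalings.

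The 2 peroxide responses shared most genes: 1604 rose in both against 672 expected if the calls were independent, 1813 fell in both against 822 expected, and 14 and 13 changed in opposite directions. Across 5324 genes the total least squares slope of the response with carnitine on the response without it was 1.066 (jackknife SE 0.0367, r = 0.931, Spearman rho = 0.920), the 2 responses having no array in common. Genes are not independent replicates, so these values describe the arrays used. OYE3, at 9.64 without and 10.45 with carnitine, TSA2, at 6.17 and 5.37, and GND2, at 4.71 and 7.92, lay off a line of equal response.

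**Figure D2:**
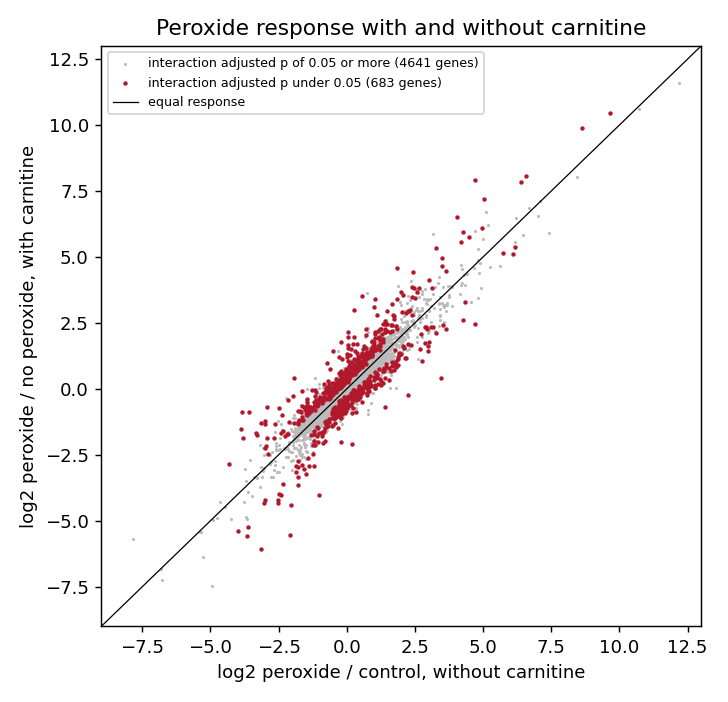
Peroxide response of 5324 genes with and without carnitine. The x axis is the log2 change with peroxide in cultures without carnitine and the y axis the log2 change in cultures with carnitine; each point is a gene, red where the interaction passed (683 genes), and the line marks an equal response. GND2 lies above the line (4.71 and 7.92) and HOF1 below it (-2.09 and -5.54).

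Carnitine under peroxide, compared with peroxide alone, answers how carnitine-fed cells differ while under peroxide: 12 of 17 hexose transport and 26 of 36 proteasome genes rose, as did GND2 and TKL2 of the pentose phosphate pathway, and 21 of 30 sulfur, 29 of 47 amino acid and 14 of 21 G2/M genes fell, though 0 lists passed with an estimated correlation. GND2 rose by 3.25 ± 0.22 (adjusted p = 0.00131), from 304 ± 25.7 to 2929 ± 626, and TKL2 (YBR117C), for the minor transketolase, by 2.36 ± 0.34 (adjusted p = 0.00353), from 432 ± 48.1 to 2219 ± 316. YJR115W rose by 2.40 ± 0.51, from 113 ± 85.7 to 508 ± 73.9. HOF1 fell by 3.25 ± 0.25 (adjusted p = 0.00149), from 254 ± 80.0 to 26.5 ± 7.05, SFG1 fell by 2.80 ± 0.35 and SWI5 (YDR146C), for a factor that drives late mitotic and early G1 genes, fell by 2.17 ± 0.30. PHO84 and SPL2 fell here too, with changes of -1.70 ± 0.17 (adjusted p = 0.00203) and -2.43 ± 0.23 (adjusted p = 0.00203).

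FAT3, linked to fatty acid uptake, rose by 2.72 ± 0.54, PUT4, for a proline permease, by 2.53 ± 0.28, XYL2, for a xylitol dehydrogenase, by 2.52 ± 0.68 and GIP2, for a phosphatase-targeting subunit, by 2.26 ± 0.36. YOL131W, YBR284W and GIC1 rose by 2.73 ± 0.25, 2.34 ± 0.45 and 2.19 ± 0.46. ECM13 fell by 2.31 ± 0.42, from 1297 ± 325 to 268 ± 109, and TOS6, MGA1, SRL4, YAL037C-A and YGR126W fell, with changes of -2.59 ± 0.49, -2.17 ± 0.56, -2.84 ± 0.28, -2.99 ± 0.43 and -2.27 ± 0.36. OYE3 (YPL171C) rose by 0.87 ± 0.12 and YOR1 (YGR281W), for a drug efflux pump, by 0.99 ± 0.090, whereas the catalase gene CTA1 fell by 0.98 ± 0.31 (adjusted p = 0.0411) and YAT2 fell by 0.91 ± 0.12 (adjusted p = 0.00294). CYC3, for the enzyme that attaches haem to cytochrome c, rose by 0.95 ± 0.12 (adjusted p = 0.00291). ALD4, for mitochondrial aldehyde dehydrogenase, rose by 0.79 ± 0.095, and FET4, for a low-affinity iron transporter, fell by 2.12 ± 0.31. Several of these genes are dim: with 50 added the changes were -1.97 for HOF1, 0.66 for YOL131W, 1.63 for FAT3, 0.65 for PUT4, 1.51 for XYL2, 1.44 for YBR284W and 0.97 for GIP2. They were 0.52 for GIC1, -0.87 for YAL037C-A, -0.79 for SRL4, -1.20 for TOS6, -1.11 for SPL2, -1.08 for YGR126W and -1.39 for MGA1, and the calls of GIC1 and MGA1 ended.

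Hexose transport and phosphorylation genes rose in 12 of 17 cases and fell in 1 (13 and 2 adjusted over the list alone), HXT2 by 0.94 ± 0.085, MTH1 by 1.70 ± 0.21 and MIG1 by 0.92 ± 0.12. The hexose list median was 0.78 (camera adjusted p = 0.000310, adjusted p = 0.674 with an estimated correlation). Of 36 proteasome genes 26 rose and 1 fell (28 and 1 adjusted over the list alone), the activator gene BLM10 by 0.90 ± 0.093 and PUP1, for a catalytic subunit, by 0.52 ± 0.062. The proteasome median was 0.23 (camera adjusted p = 4.76e-07, adjusted p = 0.674 with an estimated correlation). General stress genes rose in 10 of 29 cases and fell in 0 (10 and 0 adjusted over the list alone), PGM2, for phosphoglucomutase, by 0.86 ± 0.11. The general stress median was 0.29 (camera adjusted p = 0.00111, adjusted p = 0.674 with an estimated correlation). In trehalose and glycogen 8 of 18 rose and 1 fell (9 and 1 adjusted over the list alone), GPH1, for glycogen phosphorylase, by 1.30 ± 0.17 and GDB1, for the debranching enzyme, by 1.27 ± 0.18. The trehalose and glycogen median was 0.31 (camera adjusted p = 0.00340, adjusted p = 0.674 with an estimated correlation). Mitochondrial ribosomal protein genes gave 24 of 70 that rose and 0 that fell (27 and 0 adjusted over the list alone), MRP1 by 0.67 ± 0.079. The mitochondrial ribosomal median was 0.21 (camera adjusted p = 1.32e-06, adjusted p = 0.674 with an estimated correlation). Ribosome biogenesis genes rose in 25 of 93 cases and fell in 3 (22 and 2 adjusted over the list alone), REI1 by 0.75 ± 0.085. The ribosome biogenesis median was 0.13 (camera adjusted p = 0.00116, adjusted p = 0.674 with an estimated correlation). For fatty acid and ergosterol synthesis 13 of 30 rose and 1 fell (13 and 2 adjusted over the list alone), ERG4, for the last step of ergosterol synthesis, by 0.30 ± 0.038. The ergosterol list median was 0.17 (camera adjusted p = 0.0401, adjusted p = 0.674 with an estimated correlation). DNA damage genes rose in 13 of 22 cases and fell in 1 (13 and 1 adjusted over the list alone), RAD52, for homologous recombination, by 0.62 ± 0.089. The DNA damage median was 0.40 (camera adjusted p = 0.00229, adjusted p = 0.674 with an estimated correlation). The pentose phosphate and NADPH list did not pass, with 7 higher and 2 lower of 16 (7 and 2 adjusted over the list alone). The pentose phosphate median was 0.10 and the mean 0.44 (camera adjusted p = 0.111, adjusted p = 0.674 with an estimated correlation).

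None of the 30 sulfur and methionine genes rose and 21 fell (21 adjusted over the list alone), among them MET16, for sulfate reduction, which fell by 0.75 ± 0.066, MET5, for sulfite reductase, fell by 0.65 ± 0.062 and MET8, for its sirohaem cofactor, fell by 1.78 ± 0.18. The sulfur and methionine median was -0.36 (camera adjusted p = 4.76e-07, adjusted p = 0.674 with an estimated correlation). Under Gcn4, 29 of 47 amino acid genes fell and 1 rose (30 and 1 adjusted over the list alone); HOM3, for aspartate kinase, fell by 0.63 ± 0.051, ARG1 fell by 0.83 ± 0.078 and HIS4 fell by 0.80 ± 0.079. The Gcn4 list median was -0.38 (camera adjusted p = 1.91e-08, adjusted p = 0.674 with an estimated correlation). Purine synthesis genes fell in 12 of 19 cases and rose in 1 (12 and 1 adjusted over the list alone); GCV2, for glycine decarboxylase, fell by 1.46 ± 0.17 and ADE17 fell by 1.25 ± 0.15. The purine synthesis median was -0.51 (camera adjusted p = 0.000310, adjusted p = 0.674 with an estimated correlation). G2/M genes fell in 14 of 21 cases and rose in 1 (14 and 1 adjusted over the list alone); BUD4, for bud-site choice, fell by 1.90 ± 0.21 and CHS2, for septum chitin, fell by 1.89 ± 0.27. The G2/M cell cycle median was -0.69 (camera adjusted p = 9.19e-06, adjusted p = 0.674 with an estimated correlation). Of 128 cytosolic ribosomal protein genes 65 fell and 2 rose (67 and 2 adjusted over the list alone); RPS26B fell by 0.68 ± 0.077. The cytosolic ribosomal median was -0.16 (camera adjusted p = 1.98e-10, adjusted p = 0.674 with an estimated correlation). Respiratory chain and ATP synthase genes fell in 11 of 34 cases and rose in 2 (13 and 2 adjusted over the list alone); COX6, for a cytochrome oxidase subunit, fell by 0.45 ± 0.074. The respiratory chain median was -0.18 (camera adjusted p = 0.00340, adjusted p = 0.674 with an estimated correlation). Under poly-A spike scaling the median of all genes stood at 0.77, above 0 by more than each of these falling lists lay below it, so their falls hold relative to other genes and turn to rises in median signal on that scale. The linear model called 1892 of 5324 genes, 1002 that rose and 890 that fell, 197 of them at least 2-fold, with 2521 at unadjusted p below 0.05; camera called 14 of 39 lists, 0 with estimated correlation, where 0 had unadjusted p below 0.05. Leaving out the second peroxide array lowered the number of genes to 786. The 2 carnitine comparisons shared 14 rising genes against 4.71 expected if independent and 20 falling genes against 9.19, with 0 and 8 in opposite directions.

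The interaction tests whether carnitine acted differently under peroxide than without it, which is the same as asking whether the peroxide response differed: 11 of 17 hexose transport and 9 of 18 trehalose and glycogen genes passed with positive values, and 9 of 21 G2/M, 9 of 30 sulfur and 13 of 47 amino acid genes with negative ones. Among called genes GND2 had the largest positive value, 3.21 ± 0.32 (adjusted p = 0.00891), followed by YJR115W at 2.96 ± 0.72 and GIP2 at 2.94 ± 0.51. TKL2 had 2.47 ± 0.48 (adjusted p = 0.0265) and SOL4, for a 6-phosphogluconolactonase, 1.67 ± 0.23 (adjusted p = 0.0186): without peroxide and with carnitine SOL4 had a change of -1.12. ENB1 had 2.10 ± 0.28 (adjusted p = 0.0186), with 3709 ± 733 in control, 1248 ± 105 with carnitine, 7458 ± 1861 with peroxide and 10719 ± 1643 with both. Among called genes HOF1 had the lowest value, -3.46 ± 0.35 (adjusted p = 0.00891), and DAN1 (YJR150C), for a wall mannoprotein, had -3.01 ± 0.55, with 3743 ± 308 for carnitine and 243 ± 109 for both. PCL2 (YDL127W), a G1 cyclin gene, had -2.09 ± 0.31 (adjusted p = 0.0196), with 1348 ± 436 for peroxide and 389.6 ± 46.6 for both.

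ATO2, for an ammonium or acetate transporter, had 2.37 ± 0.24, MAL11, for a maltose transporter, 2.70 ± 0.44, MRK1, for a glycogen synthase kinase 3 homologue, 2.35 ± 0.46, and YBR284W and YOL131W 2.77 ± 0.64 and 2.70 ± 0.35. PHO89 had 2.33 ± 0.54 (adjusted p = 0.0365), whereas SPL2 and PHO84, at 0.02 ± 0.33 and 0.14 ± 0.24, did not pass (adjusted p = 0.977 and adjusted p = 0.730). SFG1 had -2.95 ± 0.50, SWI5 -2.34 ± 0.42, HMS1, for a filamentous growth regulator, -2.29 ± 0.55, AIM20 -1.91 ± 0.46, and YAL037C-A, SRL4 and YGR126W -3.04 ± 0.61, -2.47 ± 0.39 and -2.27 ± 0.50. HSP30 had 1.48 ± 0.33, FRE3 1.11 ± 0.26 and OYE3 0.81 ± 0.18, while TSA2 and TIR2, which rose with carnitine alone, had -0.80 ± 0.19 and -0.99 ± 0.15. YAT2 had -0.83 ± 0.17 (adjusted p = 0.0276), CYC3 0.78 ± 0.17 and GSH1 -0.31 ± 0.071, and CRC1, for the mitochondrial carnitine carrier, had 1.35 ± 0.12, with 4.47 ± 0.364 for peroxide and 11.4 ± 0.244 for both. CRC1, YGR126W and FAT3 were at the floor in both groups without peroxide, so their interaction values depend on it. The values for TOS6, FAT3 and CTA1, -2.56 ± 0.70, 2.72 ± 0.77 and -1.51 ± 0.43, did not pass (adjusted p = 0.0529, adjusted p = 0.0584 and adjusted p = 0.0597). With 50 added the values were 1.08 for GIP2, 1.53 for YBR284W, 0.66 for YOL131W, 1.42 for MAL11, 1.01 for MRK1, 1.49 for PHO89, 0.17 for CRC1 and -2.16 for HOF1. They were -0.88 for YAL037C-A, -0.74 for SRL4, -1.11 for HMS1 and -1.08 for YGR126W, and the calls of MRK1, PHO89, YAL037C-A and AIM20 ended.

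Hexose transport and phosphorylation had 11 positive and 0 negative calls among 17 genes (14 and 1 adjusted over the list alone), with HXT2 at 0.93 ± 0.12, GLK1, for glucokinase, at 0.64 ± 0.092 and MTH1 at 1.65 ± 0.30. The hexose list median was 0.87 (camera adjusted p = 9.52e-06, adjusted p = 0.664 with an estimated correlation). Trehalose and glycogen had 9 and 0 of 18 (15 and 0 adjusted over the list alone), GSY1 at 1.97 ± 0.32 and TPS1, for trehalose phosphate synthase, at 0.75 ± 0.13. The trehalose and glycogen median was 0.84 (camera adjusted p = 3.44e-06, adjusted p = 0.664 with an estimated correlation). General stress had 9 and 1 of 29 (12 and 1 adjusted over the list alone), PGM2 at 1.54 ± 0.15 and GRE3, for an aldose reductase, at 0.76 ± 0.089. The general stress median was 0.66 (camera adjusted p = 9.53e-05, adjusted p = 0.664 with an estimated correlation). The iron regulon had 12 and 1 of 28 (16 and 3 adjusted over the list alone), FRE1 at 1.15 ± 0.13, FET3 at 0.87 ± 0.10 and FIT3 at 1.17 ± 0.16. The iron regulon median was 0.66 (camera adjusted p = 0.000483, adjusted p = 0.664 with an estimated correlation). For the proteasome the calls were 13 and 0 of 36 (24 and 1 adjusted over the list alone), PUP1 at 0.57 ± 0.088. The proteasome median was 0.28 (camera adjusted p = 4.20e-08, adjusted p = 0.664 with an estimated correlation). Pentose phosphate and NADPH genes had 4 and 0 of 16 (5 and 0 adjusted over the list alone). The pentose phosphate median was 0.13 and the mean 0.52 (camera adjusted p = 0.0219, adjusted p = 0.664 with an estimated correlation). Mitochondrial ribosomal proteins had 5 and 0 of 70 (3 and 0 adjusted over the list alone). The mitochondrial ribosomal median was 0.23 (camera adjusted p = 4.99e-07, adjusted p = 0.664 with an estimated correlation). DNA damage had 4 and 0 of 22 (8 and 0 adjusted over the list alone), MAG1, for a DNA glycosylase, at 1.004 ± 0.22. The DNA damage median was 0.34 (camera adjusted p = 0.00402, adjusted p = 0.664 with an estimated correlation).

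Among lists with negative values, each at adjusted p = 0.664 with an estimated correlation, G2/M cell cycle had 0 positive and 9 negative calls of 21 (0 and 13 adjusted over the list alone), BUD4 at -1.73 ± 0.29 and CHS2 at -1.81 ± 0.38. The G2/M cell cycle median was -0.83 (camera adjusted p = 4.99e-07). Daughter-cell separation and early G1 had 0 and 4 of 16 (0 and 6 adjusted over the list alone), the cyclin gene PCL9 at -0.67 ± 0.12. The daughter-cell list median was -0.22 (camera adjusted p = 0.0133). Sulfur and methionine had 0 and 9 of 30 (0 and 21 adjusted over the list alone), MET16 at -0.76 ± 0.093 and MET2, for homoserine acetylation, at -0.71 ± 0.11. The sulfur and methionine median was -0.37 (camera adjusted p = 2.44e-07). The Gcn4 list had 2 and 13 of 47 (2 and 18 adjusted over the list alone), ARG1 at -0.80 ± 0.11 and HOM3 at -0.52 ± 0.072. The Gcn4 list median was -0.31 (camera adjusted p = 5.31e-07). Purine synthesis had 1 and 9 of 19 (1 and 12 adjusted over the list alone), ADE17 at -1.24 ± 0.21. The purine synthesis median was -0.55 (camera adjusted p = 0.000212). Cytosolic ribosomal proteins had 1 and 18 of 128 (1 and 32 adjusted over the list alone), RPS26B at -0.67 ± 0.11. The cytosolic ribosomal median was -0.16 (camera adjusted p = 4.65e-09). Poly-A spike scaling put the median of all genes at 0.65, which exceeds the fall of each of these lists except G2/M in size. The linear model called 683 of 5324 genes, 411 positive and 272 negative, 144 of at least 2-fold, with 1708 at unadjusted p below 0.05. Camera called 14 of 39 lists, 0 with estimated correlation, where 1 had unadjusted p below 0.05. Leaving out 1 array gave between 17 and 969 genes, so the membership of this set depends on single arrays.

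**Figure D3:**
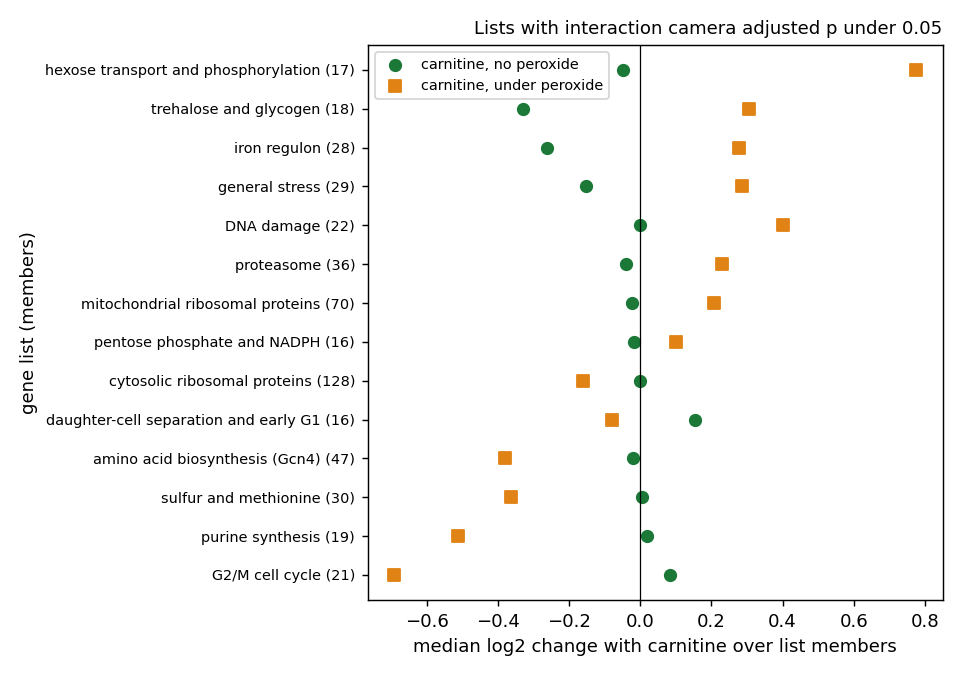
Median log2 change with carnitine of the 14 gene lists that camera called for the interaction with its preset correlation (0 with an estimated one). The x axis is the median log2 change over list members and the y axis names the lists with their number of members; circles are carnitine without peroxide and squares carnitine under peroxide, from 2 arrays per group. Hexose transport and phosphorylation lies at -0.05 without and 0.78 under peroxide, and G2/M cell cycle at 0.08 and -0.69.

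**Figure D4:**
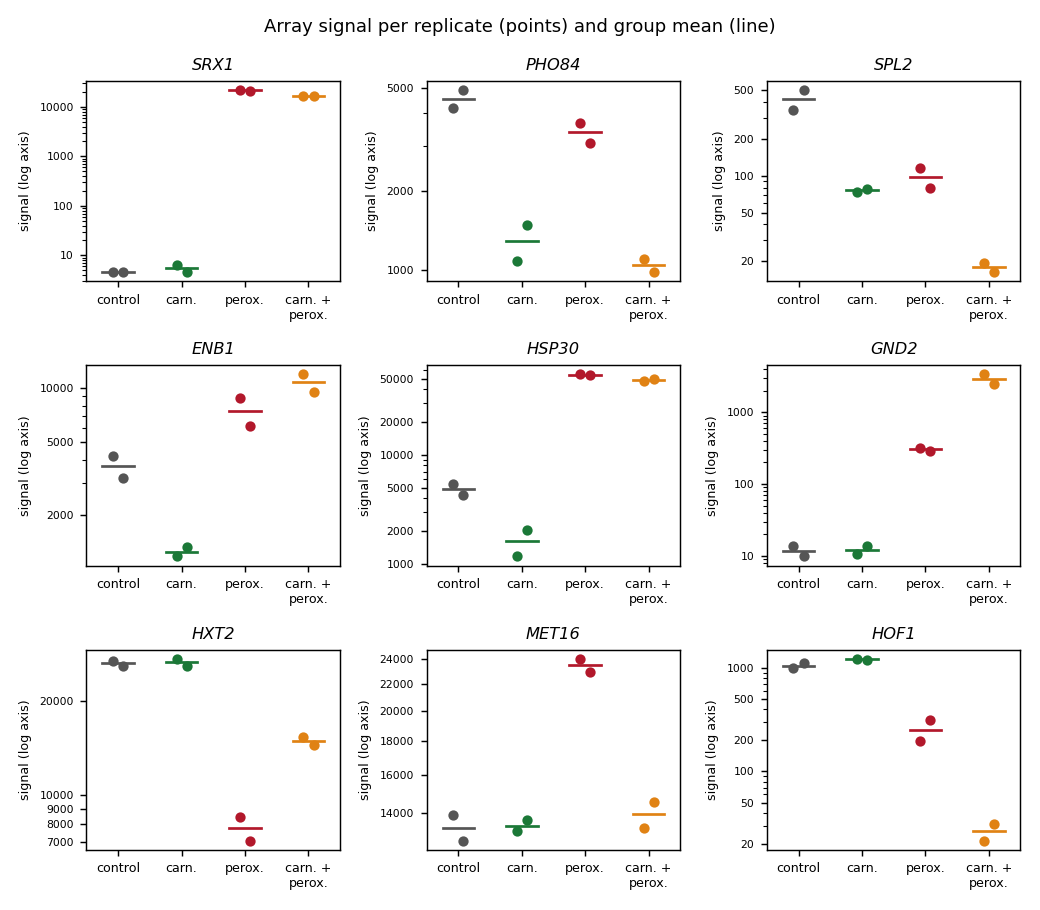
Signals of 9 genes on the 8 arrays. The x axis gives the 4 groups and the y axis the deposited linear signal on a log scale; each point is 1 array and each bar a group mean (n = 2). PHO84 is lower with carnitine with or without peroxide, and GND2 reaches 2929 ± 626 with both treatments against 304 ± 25.7 with peroxide alone.

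The carnitine effect averaged over both peroxide conditions, which either can drive alone, answers which transcripts moved. SPL2 and PHO84 fell, and 41 of 93 ribosome biogenesis genes rose slightly. SPL2 fell by 2.45 ± 0.16 (adjusted p = 0.00102), PHO84 fell by 1.76 ± 0.12 (adjusted p = 0.00103) and FET4 (YMR319C) fell by 1.54 ± 0.22 (adjusted p = 0.00685). TPO4 (YOR273C), for a polyamine exporter, fell by 0.83 ± 0.048 (adjusted p = 0.000696), MGA1, for a heat-shock factor-like protein, fell by 2.40 ± 0.39, BAG7 fell by 1.81 ± 0.22, ECM13 fell by 1.62 ± 0.30 and GAL7, for a galactose enzyme, fell by 1.61 ± 0.24. HPF1 rose by 1.36 ± 0.10 (adjusted p = 0.00135), HES1 by 1.55 ± 0.20, SNO4 by 1.16 ± 0.13 and FMP45, for a membrane protein, by 1.15 ± 0.22. GND2, TKL2, PUT4, YOL131W, FAT3 and YJL118W rose by 1.65, 1.12, 1.48, 1.38, 1.36 and 1.11, and HOF1, SRL4 and YAL037C-A fell (-1.52, -1.61, -1.47). The interaction passed for these 9 but FAT3, so their averages join unlike effects, as do lists called for it. With 50 added the averages were 0.90 for HES1, 0.49 for FMP45, -1.50 for SPL2, -1.33 for MGA1, -1.11 for BAG7, -0.60 for GAL7 and -0.89 for HOF1.

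With an estimated correlation each list named here had adjusted p = 0.647. Of 93 ribosome biogenesis genes 41 rose and 0 fell (52 and 0 adjusted over the list alone), REI1 by 0.57 ± 0.060 and MAK16 by 0.55 ± 0.065. The ribosome biogenesis median was 0.15 (camera adjusted p = 2.37e-10). RNA polymerase I and III genes rose in 9 of 27 cases (9 and 1 adjusted over the list alone), RRN7 by 0.90 ± 0.15. The polymerase I and III median was 0.10 (camera adjusted p = 0.00571). G1/S genes rose in 8 of 28 cases and fell in 1 (9 and 1 adjusted over the list alone), RNR1, for ribonucleotide reductase, by 0.63 ± 0.085. The G1/S cell cycle median was 0.15 (camera adjusted p = 0.00361). Phosphate regulon genes fell in 6 of 16 cases and rose in 1 (6 and 1 adjusted over the list alone), and PHM8, for a phosphatase of starved cells, fell by 0.90 ± 0.10. The phosphate regulon median was -0.10 and the mean -0.49 (camera adjusted p = 0.00680). In the tricarboxylic acid cycle 8 of 18 fell and 1 rose (8 and 2 adjusted over the list alone), and CIT1 fell by 0.31 ± 0.030 and IDH1 fell by 0.46 ± 0.050. The tricarboxylic acid cycle median was -0.08 (camera adjusted p = 0.0497). Sulfur and methionine genes fell in 15 of 30 cases (17 adjusted over the list alone), and MET8 fell by 1.01 ± 0.13. The sulfur and methionine median was -0.18 (camera adjusted p = 4.77e-05). Gcn4 genes fell in 23 of 47 cases and rose in 1 (27 and 1 adjusted over the list alone), and ARG3 fell by 0.92 ± 0.12. The Gcn4 list median was -0.18 (camera adjusted p = 3.92e-08). Cytosolic ribosomal protein genes fell in 38 of 128 cases and rose in 1 (49 and 1 adjusted over the list alone), and RPL36A fell by 0.30 ± 0.038. The cytosolic ribosomal median was -0.08 (camera adjusted p = 3.92e-08).

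The other lists that passed, each at adjusted p = 0.647 with an estimated correlation, had medians of 0.32 for hexose transport (8 of 17 higher, 1 lower; adjusted p = 0.0184), 0.10 for the proteasome (10 and 1 of 36, adjusted p = 0.000372) and 0.10 for mitochondrial ribosomal proteins (12 and 0 of 70, adjusted p = 0.000372). Fatty acid and ergosterol synthesis had 0.06 (9 and 0 of 30, adjusted p = 0.0379) and DNA damage 0.23 (4 and 0 of 22, adjusted p = 0.00633). Purine synthesis had -0.27 (1 and 11 of 19, adjusted p = 0.00129), G2/M cell cycle -0.35 (1 and 8 of 21, adjusted p = 0.000678) and the respiratory chain -0.11 (1 and 10 of 34, adjusted p = 0.00361). In the same order, calls adjusted over the list alone were 10 and 2, 13 and 1, 11 and 0, 9 and 0, 4 and 0, 1 and 12, 1 and 10 and 1 and 10. The linear model called 1353 of 5324 genes, 693 that rose and 660 that fell, 47 of them at least 2-fold, with 2196 at unadjusted p below 0.05. Camera called 16 of 39 lists, 0 with estimated correlation, where 0 had unadjusted p below 0.05. Leaving out the first array with both treatments lowered the number of genes to 589, and the tricarboxylic acid cycle and ergosterol calls ended under both spike scalings.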

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

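The test of a larger peroxide response, that of single arrays under peroxide and that of a change opposite to the peroxide response were written down before the result was seen, the others after. What singled out each value below is a tested difference of the carnitine effect between cultures with and without peroxide, unless the sentence says otherwise.

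Carnitine separated more genes under peroxide (1892) than without it (80), and 683 genes passed the interaction test. An array scaling that shifts all genes alike is argued against, since it leaves the spread across genes as it is: the SD of the carnitine effect was 0.4327 under and 0.2304 without peroxide, and the ratio of SD or MAD was 1.631 at the lowest when 1 array was left out. RNA integrity is argued against by a median difference in log2 3' to 5' ratio of 0.01598 over 7 control transcripts (range -0.115 to 0.164). A larger peroxide response (slope 1.066) alone is argued against, as 48.5% of 1235 genes moved with their peroxide response. The carnitine effect under peroxide had r = 0.0163 with the average peroxide effect (Spearman rho -0.052, 1 of 3 correlations). It includes that without peroxide (r = -0.279), and genes are not independent. A single array is argued against by 786 genes without the second peroxide array, the lowest of the 4, against 811 and 1236 without either array with both treatments. This does not cover the interaction, whose 683 genes became 18 without control replicate 1, 26 and 17 without the carnitine replicates and 22 without the first array with both treatments. A carnitine effect that depends on peroxide stays open, as a hypothesis. Its absolute direction for most genes is not set. Poly-A scaling gave 4183 higher and 47 lower genes, hybridisation scaling 560 and 347.

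Of the phosphate and iron lists, 3 of 16 and 5 of 28 genes were called lower with carnitine without peroxide, 13 and 23 did not pass, and the medians over all members were -0.10 and -0.26. Under peroxide PHO84 and SPL2 fell as well, with changes of -1.70 and -2.43, while PHO89 and the 5 called iron genes had the positive interaction values given below. One array as the source is argued against for both lists as a whole, whose camera adjusted p with the preset correlation was 0.004712 at most when 1 array was left out; this rests on that correlation, since with an estimated one and all arrays neither list passed (adjusted p = 0.427 and 0.500). A change opposite to the peroxide response, as from the growth or stress state of the cultures, cannot be told apart. Across genes the carnitine effect correlated at -0.279 with the average peroxide effect (Spearman rho -0.322). Leaving out 1 array gave -0.321 to -0.138. Both estimates share the control and carnitine arrays, whose noise can move r either way.

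Ribosomal RNA probe sets, which lie outside the tested genes, read higher with peroxide: a 25S set rose by 3.635 log2 (2876 ± 1590 to 32970 ± 3840, adjusted p = 0.000562) and the 5.8S set by 1.017 (adjusted p = 0.00065), 2 of 7 detected sets. For the 25S set, array scaling is argued against, since the largest change of any spiked transcript between peroxide and control was 0.981. For the 5.8S set, with its rise of 1.017 against that 0.981, scaling cannot be told apart, the margin being smaller than its SE of 0.135. With carnitine the peroxide rises were 1.61 (adjusted p = 0.0199) and 0.451 (adjusted p = 0.0225), and 2 of the 18S sets fell, with changes of -0.72 (adjusted p = 0.00119) and -0.86 (adjusted p = 0.00853). The other 5 sets were not called higher with peroxide alone, and no biological explanation was tested.

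Among probe sets with no gene listed, outside the comparisons, 416 lay above the floor; 84 were higher and 50 lower with peroxide, 9 passed with carnitine and 53 with carnitine under peroxide. The probe set with the largest rise among these rose by 12.31 log2, from 4.358 and 5.353 in control to 24563 and 24582 with peroxide, and read 25711 and 25785 with both treatments.

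The interaction values of metabolic genes were GND2 3.21, TKL2 2.47, SOL4 1.67, ALD4 0.78, GSY1 1.97, PGM2 1.54, GPH1 1.35, GDB1 1.17, ATH1 0.92, TPS1 0.75, GLK1 0.64, HXT2 0.93, MTH1 1.65, MIG1 0.87, MAL11 2.70, GRE3 0.76, GIP2 2.94, MRK1 2.35, ATO2 2.37 and PUT4 2.09. For sulfur, amino acid, purine and thiamine genes they were MET16 -0.76, MET2 -0.71, MET5 -0.64, MET8 -1.54, GSH1 -0.31, ARG1 -0.80, HIS4 -0.74, HOM3 -0.52, ILV3 -0.44, ADE17 -1.24, GCV2 -1.52, JLP1 1.46 and PET18 -1.01. Cell division and morphology genes had HOF1 -3.46, SFG1 -2.95, SWI5 -2.34, BUD4 -1.73, CHS2 -1.81, ALK1 -1.22, PCL2 -2.09, PCL9 -0.67, HMS1 -2.29, SRL4 -2.47 and SAG1 -0.61. Metal and phosphate genes had ENB1 2.10, FRE1 1.15, FRE3 1.11, FET3 0.87, FIT3 1.17, TIS11 1.30 and PHO89 2.33. Defence, protein and DNA upkeep and efflux genes had OYE3 0.81, YDL218W 1.26, TSA2 -0.80, HBN1 -0.55, HSP30 1.48, HSP42 0.85, PUP1 0.57, BLM10 0.85, RAD52 0.62, RNR1 0.70, MAG1 1.004, YOR1 0.81 and PDR16 -0.68. Mitochondrial, ribosomal, lipid and wall genes had YAT2 -0.83, CRC1 1.35, CYC3 0.78, HEM2 0.53, MRP1 0.59, RPS26B -0.67, LCP5 -0.46, PSD1 0.48, TIR2 -0.99 and DAN1 -3.01. The remaining genes had SPS4 -1.51, YNL092W 1.09, LSO1 1.48, SPS100 2.18, AIM20 -1.91, YOL131W 2.70, YJR115W 2.96, YBR284W 2.77, YAL037C-A -3.04, YGR126W -2.27 and YJL118W 1.45.

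The gene lists that camera called for the interaction with its preset correlation, 0 of which passed with an estimated one (lowest adjusted p = 0.664), had positive medians for pentose phosphate and NADPH 0.13, general stress 0.66, trehalose and glycogen 0.84, proteasome 0.28, mitochondrial ribosomal proteins 0.23, hexose transport and phosphorylation 0.87, iron regulon 0.66, DNA damage 0.34. Negative medians were those of cytosolic ribosomal proteins -0.16, sulfur and methionine -0.37, amino acid biosynthesis (Gcn4) -0.31, purine synthesis -0.55, G2/M cell cycle -0.83, daughter-cell separation and early G1 -0.22.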

How the results depend on the processing

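The spike scalings and the crossed numbers were chosen after seeing the data; all other alternatives were fixed before. None of the 120 named gene results, nor the camera direction of the 96 list results, turned under the alternatives run on them. Some list medians did under spike scaling. Of the 120 gene results, 16 no longer passed with no filter, 12 with the offset of 50 and 11 without a variance trend. Quantile normalization ended 2, all probe sets 1, median centring and both spike scalings 0, and only the comparison's arrays 12 of 80. The stricter filter left only 6, all passing. Of 96 list results, 13 of the 89 left under the stricter filter, 15 under poly-A scaling, 12 under hybridisation scaling, 4 under quantile normalization and 96 with an estimated correlation no longer passed. Leaving out 1 array ended 183 of 960 gene results and 29 of 768 list results; the lone array left in a group is assumed to vary like the others. Signals near the floor, about 4, limit the folds of dim genes, and 125 genes below it were not tested.

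Counts of called genes that moved by more than 1.5 times, the cause not tested where not named, were as follows. With no filter, carnitine alone gave 41 (80 with it) and the interaction 449 (683). The stricter filter, which tests fewer genes, gave 2585 for peroxide (3980) and 2640 for peroxide with carnitine (3987). Only the arrays of the comparison gave 15 for carnitine alone, with fewer degrees of freedom. At least 2-fold gave 22, 1303, 1359, 197, 144 and 47 in the order of the comparisons, and an adjusted p of 0.10 gave 164 for carnitine alone and 1249 for the interaction. Poly-A spike scaling gave 44 for carnitine alone, 2532 for peroxide with carnitine, 4230 for carnitine under peroxide (4183 higher, 47 lower, against 1002 and 890), 1251 for the interaction (1231 and 20, against 411 and 272) and 3389 for the averaged effect (3339 and 50, against 693 and 660); the cause was not tested. Peroxide alone gave 613 higher and 2711 lower (against 1877 and 2103) on that scale, and carnitine alone 20 and 24 (against 25 and 55). Hybridisation spike scaling gave 907 for carnitine under peroxide (560 and 347) and 387 for the interaction (137 and 250); splits were 75 and 41 for carnitine alone, 2826 and 761 for peroxide, 2403 and 971 for peroxide with carnitine (against 1906 and 2081) and 744 and 181 for the averaged effect; the cause was not tested.

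Leave-one-out ranges were 17 to 54 for carnitine alone, 3639 to 3938 for peroxide, 3597 to 3986 for peroxide with carnitine, 786 to 1763 for carnitine under peroxide, 17 to 969 for the interaction and 589 to 1425 for the averaged effect; the slope of the peroxide responses ran from 1.039 to 1.085. Carnitine alone gave 17 and 53 without control replicate 1 and 2, 24 and 25 without carnitine replicate 1 and 2, and 44 without either array with both treatments. Carnitine under peroxide gave 786 without peroxide replicate 2, and 811 and 1236 without the first and second array with both treatments. The interaction gave 18 and 178 without the control replicates, 26 and 17 without the carnitine replicates, 169 without peroxide replicate 2, and 22 and 208 without the arrays with both treatments. The averaged effect gave 760 and 790 without the control replicates, 594 without carnitine replicate 2, 701 without peroxide replicate 2, and 589 and 806 without the arrays with both treatments.

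Whether replicate numbers pair the cultures is not settled by the correlations of same-numbered deviations, which ran from -0.112 to 0.132 over the pairs of groups. With the replicate block the counts were 106, 4004, 4009, 1972, 863 and 1442 in the order of the comparisons. With the numbers of the carnitine arrays crossed and the replicate block, carnitine alone gave 61.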

Other observations

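The test of other splits was chosen after the result was seen; that of a shared carnitine effect was written down before. With peroxide, 10 of 21 drug efflux genes under Pdr1 rose and 4 fell (10 and 4 adjusted over the list alone), PDR16, for a lipid transfer protein, by 2.36 ± 0.077 and TPO4 by 1.13 ± 0.069. The Pdr1 list median was 0.44 (camera adjusted p = 0.156, adjusted p = 0.593 with an estimated correlation). Of 22 genes of the unfolded protein response 4 rose and 9 fell (4 and 9 adjusted over the list alone); ERO1, for oxidative protein folding, rose by 1.47 ± 0.065. The unfolded protein response median was -0.15 (camera adjusted p = 0.335, adjusted p = 0.634 with an estimated correlation). The cell wall integrity list gave 5 higher and 5 lower of 19 (5 and 5 adjusted over the list alone), BAG7 rising by 4.90 ± 0.31 and PST1 by 1.26 ± 0.12. The cell wall integrity median was -0.06 and the mean 0.34 (camera adjusted p = 0.888, adjusted p = 0.950 with an estimated correlation). Thiamine and pyridoxine genes moved both ways, 8 higher and 6 lower of 15 (8 and 6 adjusted over the list alone), with a rise of 2.14 ± 0.10 for the pyridoxine gene SNZ3. The thiamine and pyridoxine median was 0.45 (camera adjusted p = 0.601, adjusted p = 0.805 with an estimated correlation). Peroxisomal beta-oxidation gave 10 higher and 3 lower of 17 (10 and 3 adjusted over the list alone, median 0.45, adjusted p = 0.156, adjusted p = 0.593 with an estimated correlation), and glycolysis and fermentation 6 and 2 of 19 (6 and 1 adjusted over the list alone), TDH1, for glyceraldehyde phosphate dehydrogenase, rising by 1.16 ± 0.049. The glycolysis and fermentation median was 0.07 (camera adjusted p = 0.216, adjusted p = 0.634 with an estimated correlation). Glyoxylate cycle and gluconeogenesis gave 3 and 3 of 11 (3 and 3 adjusted over the list alone), IDP2, for cytosolic isocitrate dehydrogenase, rising by 2.67 ± 0.25. The glyoxylate cycle median was 0.06 (camera adjusted p = 0.595, adjusted p = 0.802 with an estimated correlation).

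With carnitine under peroxide, the wall protein gene SED1 rose by 0.61 ± 0.087 and PST1 fell by 0.60 ± 0.12, within a cell wall integrity list of 3 higher and 6 lower of 19 (5 and 7 adjusted over the list alone, adjusted p = 0.743, adjusted p = 0.940 with an estimated correlation). Cytochrome c and haem assembly gave 5 higher and 4 lower of 20 (5 and 4 adjusted over the list alone), HEM2, for haem synthesis, rising by 0.55 ± 0.071. The haem assembly median was 0.04 (camera adjusted p = 0.878, adjusted p = 0.925 with an estimated correlation). Without peroxide the sterol regulator gene UPC2 rose with carnitine by 0.69 ± 0.097 (adjusted p = 0.0216), while THI4, for thiamine synthesis, had 0.69 ± 0.15 and did not pass (adjusted p = 0.0775). Of 4 α mating type genes 1 rose and 2 fell with peroxide (1 and 2 adjusted over the list alone, median -0.28, adjusted p = 0.595, adjusted p = 0.712 with an estimated correlation), MF(ALPHA)2 by 0.43 ± 0.047 and SAG1, which fell by 0.65 ± 0.084; 1 and 2 of 6 a mating type genes did so (1 and 2 adjusted over the list alone). The a mating type median was -0.34 (camera adjusted p = 0.515, adjusted p = 0.716 with an estimated correlation).

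A carnitine effect shared by both peroxide conditions was tested by the correlation across 5324 genes of the 2 carnitine effects, which use no array in common: r = 0.2143 (Spearman rho 0.212; 0.144 to 0.246 when 1 array was left out). Genes are not independent replicates and arrays hybridised together can share noise, so a shared effect cannot be told apart from shared noise for the set of genes as a whole. Of 18 splits of the arrays balanced within peroxide condition, only the real one (1) gave as many genes for the averaged effect: 126 in the additive model, against 1 as the highest of the others. The 18 splits are too few for a share under 0.05.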
